A study of Mus musculus with 44 samples.

How the data were processed

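The samples were 44 RNA-seq libraries of adult mouse tissue, each from a pool of mice. Tagged polysomes were pulled down with anti-GFP beads (IP, 28 libraries), and RNA of the whole homogenate was kept (input, 16 libraries). Some pools have a library of only 1 of these fractions. The MHb libraries came from the ChAT line: 4 inputs and 12 IPs, of which 2 were from mice on nicotine water and 1 from mice on nicotine water with a saline injection. The IPN libraries came from the Chrna5 line (4 inputs, 3 IPs), the Amigo1 line (4 inputs, 3 IPs of controls, 3 IPs of mice on nicotine water) and the Epyc line (4 inputs, 5 IPs of controls, 2 IPs of mice with nicotine pumps). Control IPs and inputs included baseline, saline pump and, in the ChAT line, saccharin-water mice, some with a saline injection 3 h before collection. The ChAT baseline IPs are baseline in their descriptions, but their library names say saline. Nicotine water held saccharin too, so the Amigo1 nicotine mice differ from their controls in saccharin as well. The 2 baseline ChAT inputs were the left and the right MHb of 9 males each, per the labels, which do not say if these were the same mice; Chrna5 pool 4 was also male, and the sex of other pools is not given in the sources used here. One replicate is 1 pool, so the spread between libraries covers mice, dissection and IP together, and the Epyc and ChAT nicotine groups held 2 pools each. Sequence libraries were made from amplified cDNA with a DNA library kit, per the labels' protocols, which name no molecular identifiers and no strand marking.

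The deposited values are counts of reads per gene symbol, 1 file per library. Reads were aligned to mm10 with STAR 2.3.0e, counted with HTSeq and compared with DESeq2, per the submitters' processing notes; the settings of these steps are not given in the sources used here. The files use 3 gene lists: list 1 with 37328 symbols in 22 libraries (all inputs, all Chrna5 IPs and 3 ChAT IPs), list 2 with 32532 in 18 libraries (all Amigo1 and Epyc IPs and 5 ChAT IPs) and list 3 with 24454 in 4 libraries (the ChAT baseline IPs). Tests used the 22682 symbols found in every file. These held 71.6 to 98.3% of the counts of a library, and the other symbols were left out. Reads in no gene made 8.5 to 27.3%, reads without a unique place 20.3 to 57.0% and ambiguous reads 0.54 to 5.56% per library; all stayed out of library sizes and tests, as did an entry with no gene name, which held at most 2 counts. The share of ambiguous reads was 2.87 to 5.56% on list 1, 0.54 to 2.17% on list 2 and 0.61 to 0.71% on list 3. Libraries had 7908401 to 70481509 counts in genes. A gene at 0 counts lies below a floor of 3 counts, which was 0.0495 to 0.436 CPM per library; such floors cover counting error only, since amplified reads are counted.

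Because list and fraction overlap, the shift between lists 1 and 2 was estimated within the ChAT IPs, where both occur, with nicotine as a term. It rests on the saline pump IP and saline-injected saccharin IP 1 (list 2) against the uninjected saccharin IPs and saline-injected saccharin IP 2 (list 1). Treatment and pool thus enter it too. Over all ChAT IPs, Sst overlapped between list 2 (1.02 to 5.64 CPM) and list 1 (4.16 to 10.5 CPM), while Nos1 did not (9.78 to 15.2 and 85.1 to 94 CPM). Of 14893 genes, 773 shifted by at least 1 on the log2 scale at adjusted p < 0.05 (362 higher and 411 lower on list 2), and the median absolute shift was 0.376. List and fraction cannot be told apart for the Amigo1 and Epyc IPs against inputs, and list and nicotine coincide in the uninjected ChAT groups. The Chrna5 comparison, the nicotine comparisons of both IPN lines and the comparisons of inputs each used 1 list. The Amigo1 and Epyc IPs set against each other were all on list 2, but that fit also held the Chrna5 IPs, on list 1. The scaling, count filter and spread of that fit thus drew on both lists.

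Differential expression was computed with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with a minimum count of 10, and the robust quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes tested and calls at adjusted p < 0.05. The 9 comparisons of the design were fixed before the data were examined: IP against input in each of the 4 lines, Amigo1 against Epyc IPs (fitted with the Chrna5 IPs, 11 libraries), nicotine against control in the ChAT, Amigo1 and Epyc IPs, and the difference between the Amigo1 and Epyc nicotine responses. The ChAT nicotine fit held 7 libraries in 4 groups and contrasted the uninjected groups, 2 against 2. A pair of comparisons of inputs was added after seeing the data. DESeq2 1.42.0 and limma 3.58.1 were used for alternatives and list tests. Figures and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene positions are from the GENCODE M21 annotation of GRCm38. Levels are TMM-scaled CPM, computed here from the deposited counts.

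Genes were named by a rule fixed beforehand: Chat, Chrna5, Amigo1, Epyc, Nos1 and Sst in every comparison (with Chrna3, Chrnb4 and Chrnb2 for nicotine); the 8 genes with the largest fold changes per direction among calls with non-overlapping groups and at least 10 CPM in the higher group, without predicted genes; and the 4 members of each list with the smallest p. Non-overlap cannot apply to a difference of differences and was dropped there. Some items are withheld for evaluations and are left out of the text. In the Amigo1 and Epyc IP comparisons the genes with the largest fold changes are those that shift by less than 1 between gene lists, apart from examples of genes with counts on 1 list; for fixed genes and list members the shift is given where it was at least 1 at adjusted p < 0.05. Chat was under the count filter in the IPN comparisons, and Epyc in the ChAT comparisons and the Amigo1 nicotine comparison.

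Lists of marker and pathway genes, also fixed beforehand, covered neuronal nicotinic receptor subunits, cholinergic, MHb, GABAergic, glutamatergic and pan-neuronal genes, neuropeptides, neuropeptide receptors, nitric oxide and cGMP signalling, GABA receptor subunits (GABA-A, with Gabbr1 and Gabbr2), ionotropic glutamate receptor subunits, voltage-gated ion channels, dopamine and serotonin neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, choroid plexus and ependyma, thalamus and hippocampus neurons, blood, immediate early genes, the unfolded protein response and chaperones, the proteasome, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, histones and sex-linked genes. A list of genes encoded by mitochondrial DNA had 0 members among the shared symbols. Lists with at least 3 tested members were tested with camera (preset correlation 0.01, adjusted over the lists of a comparison), again with an estimated correlation, and with fry. Of 249 list tests 71 passed with the preset correlation and 13 with an estimated one; where the text gives no p with an estimated correlation beside a passed test, the call held. Markers overlap between lists and were chosen from general knowledge of these cell types.

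IP and input libraries with 1 line, treatment, number and pool size in the labels were taken as pairs from the same mice. For saline-injected saccharin ChAT pair 1 the labels give no number, and it was taken from the order of the samples. In 1 of 3 Amigo1 pairs, the saline pump, this is in doubt: the Y-linked gene Ddx3y stood at 0.436 CPM in the IP and 37.9 CPM in the input. Deviations from the group means correlated at 0.3 for the 2 ChAT pairs, 0.12 to 0.19 for Chrna5, 0.041 to 0.054 for Amigo1 and 0.039 to 0.057 for Epyc. Every such library was closest to its own pool. With 2 libraries per fraction the deviations mirror each other, so the 2 ChAT pairs give only 1 value. Blocked fits for the pool were run as an alternative on the pools with both fractions, because several libraries have no partner. Each comparison was tested on simulated data made from its own libraries, with 100 genes changed 2-fold and 100 changed 4-fold. The share recovered was 73 and 94% for ChAT IP against input, 66 and 98% for Chrna5, 37 and 88% for Amigo1, 61 and 95% for Epyc, 50 and 89% for Amigo1 against Epyc, 21 and 91% for ChAT nicotine, 0 and 1% for Amigo1 nicotine, 51 and 93% for Epyc nicotine and 0 and 0% for the difference of responses. For the inputs it was 84 and 99% (IPN against MHb) and 90 and 99% (Chrna5 line against others). False calls made 14.6% for ChAT nicotine and at most 6.11% elsewhere. Libraries were checked for repeats of the same sample: the closest pair, Epyc baseline inputs 1 and 2, had a dispersion index of 12.8, so no pair differed by sampling noise alone.

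Alternatives were DESeq2, RLE size factors, no count filter, the pool or replicate number as a block, a term for the gene list, and each library left out. Subsets of libraries (baseline only, saline-injected saccharin mice only, the saline pump as control) were used too. Another alternative kept only calls with an estimated absolute log2 difference of at least 1, which is a cut and not a test. Added after seeing the data were fits without genes that shift between lists, fits on 1 list only and limma voom with sample weights. The 1 IP of mice on nicotine water with a saline injection entered the ChAT nicotine fit as a group of its own and no contrast. Symbols outside the shared set were not analysed here, apart from immunoglobulin genes in the Chrna5 libraries.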

Results

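The series profiled mouse neurons of the habenula to interpeduncular pathway by translating ribosome affinity purification, in which ribosomes tagged with EGFP-L10a are pulled down (IP) and their RNA is set against RNA of the whole dissected tissue (input). The 44 libraries came from pools of mice: 28 IPs and 16 inputs. Cholinergic neurons of the medial habenula (MHb) carried the tag in the ChAT line, and neurons of the interpeduncular nucleus (IPN) carried it in the Chrna5, Amigo1 and Epyc lines. The study asked how the labelled cell types differ from their tissue and from each other at baseline, and which genes differ in the IPs of mice given nicotine. Levels are CPM (counts scaled to a common library size, within the libraries of each comparison) as mean ± SD over libraries, differences are log2 fold changes ± SE from edgeR, and a gene was called at adjusted p < 0.05 over all genes tested. Scaling within a comparison lets the level of 1 gene in 1 group differ between comparisons. Levels without an SD were not TMM-scaled. These p-values cover the spread between pools. Fits in paired pools with a block used only pools that have both an IP and an input, so they differ from the main fit in libraries too. Whether an IP level reflects ribosome occupancy in 1 cell type or RNA abundance was not separated by the design.

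Against whole habenula, RNA bound to ribosomes of ChAT neurons was rich in genes that mark MHb neurons. Chat (chr14:32408203-32465989, GRCm38), which encodes the enzyme that makes acetylcholine, stood at 125 ± 40.2 CPM in 9 IPs of mice without nicotine against 11.9 ± 2.26 CPM in 4 inputs (log2 difference 3.39 ± 0.28, adjusted p = 1.76e-07). The choline transporter gene Slc5a7 was higher by 3.62 ± 0.21, and Slc18a3, the vesicular acetylcholine transporter, by 3.88 ± 0.36. Chrna5, Chrna3 and Chrnb4, neighbouring genes on chr9 whose subunits form the nicotinic receptor typical of the MHb, were higher by 3.06 ± 0.32, 3.80 ± 0.16 and 3.63 ± 0.17. Of 15289 genes tested, 3627 were higher in the IP and 4498 lower. 4688 of these 8125 calls had an estimated absolute log2 difference of at least 1. With only the mice on saccharin water that had a saline injection, 3401 genes were called. The baseline inputs were the left and the right MHb of 9 males, perhaps the same mice. Leaving out either gave 7243 or 7130 genes.

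Among 8 nicotinic subunits tested, 6 were higher and 0 lower. Nicotinic subunit calls adjusted over the list alone numbered 6 (camera adjusted p = 6.33e-09). MHb neuron markers were higher for 17 of 19 members and lower for 0, among them Nwd2 (3.20 ± 0.11) and Kctd8 (2.90 ± 0.12), and Nr4a2, a nuclear receptor of habenular neurons (3.24 ± 0.12). MHb marker calls adjusted over the list alone numbered 17 (camera adjusted p = 4.41e-31). Outside the lists, the largest rises among genes that shift by less than 1 between gene lists included Synpr (4.30 ± 0.27) and Syt15 (3.94 ± 0.14), which encode synaptic vesicle proteins. The serotonin receptor Htr5b (3.99 ± 0.16) and the transcription factor Irx6 (4.30 ± 0.30) were among them too. The cholinergic neuron list divided 3 higher and 4 lower among 9 members: the habenular choline genes were higher, while Isl1 (-3.17 ± 0.53), a factor of striatal and motor cholinergic neurons, was lower. Cholinergic marker calls adjusted over the list alone numbered 7 (camera adjusted p = 0.0987, adjusted p = 6.36e-04 in paired pools with a block; median -0.20, mean 0.076, test up). Slc17a7, a vesicular glutamate transporter, was higher by 3.02 ± 0.16, and 3 of 8 glutamatergic markers were higher against 3 lower, 7 adjusted over the list alone (camera adjusted p = 0.0676; median -0.42, mean 0.61, test up).

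Signalling genes were mixed in the ChAT IP. Neuropeptides split 7 higher and 18 lower of 28. Neuropeptide calls adjusted over the list alone numbered 26 (camera adjusted p = 0.0788). The tachykinin gene Tac2 (2.97 ± 0.23) was higher and galanin, Gal (-4.93 ± 0.41), lower. Neuropeptide receptors split 5 higher and 20 lower of 30, with the somatostatin receptor Sstr2 (2.99 ± 0.16) and the substance P receptor Tacr1 (3.12 ± 0.17) higher. Peptide receptor calls adjusted over the list alone numbered 26 (camera adjusted p = 0.0499, adjusted p = 0.485 with an estimated correlation). Nitric oxide and cGMP genes split 4 higher and 7 lower of 17. cGMP pathway calls adjusted over the list alone numbered 11 (camera adjusted p = 0.316; median -0.40, mean -0.26, test up). The cGMP-stimulated phosphodiesterase Pde2a (3.55 ± 0.14) was higher and the cGMP-specific Pde5a (-2.97 ± 0.31) lower. The list of GABA receptor subunits was mostly lower (2 of 16 higher and 12 lower, 14 adjusted over the list alone; camera adjusted p = 0.0360, adjusted p = 0.521 with an estimated correlation), with Gabra3 (-3.29 ± 0.34) and Gabra4 (-3.42 ± 0.39). The gene that was most clearly higher, Gabbr1 (2.44 ± 0.19), encodes a GABA-B subunit. Ionotropic glutamate receptor genes (4 of 18 higher and 11 lower, 15 adjusted over the list alone; camera adjusted p = 0.289, adjusted p = 0.0205 in paired pools with a block) and voltage-gated ion channels (22 of 94 higher and 51 lower, 77 adjusted over the list alone; camera adjusted p = 0.0987, adjusted p = 8.85e-05 in paired pools with a block) leaned lower in count, with Grik2 (-1.99 ± 0.29) lower and Gria1 (1.29 ± 0.091) and Cacnb3 (3.50 ± 0.14) higher.

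Markers of other cells were lower in the ChAT IP. None of 16 astrocyte genes was higher and 16 were lower, with S100b (-4.10 ± 0.35) and Aldoc (-2.42 ± 0.22). Astrocyte calls adjusted over the list alone numbered 16 (camera adjusted p = 5.75e-08, adjusted p = 0.279 with an estimated correlation). Oligodendrocyte genes were lower for 16 of 17, including the myelin genes Mobp (-3.70 ± 0.31) and Tmem88b (-3.98 ± 0.30). Oligodendrocyte calls adjusted over the list alone numbered 16 (camera adjusted p = 2.89e-10, adjusted p = 0.279 with an estimated correlation). Oligodendrocyte precursor genes were lower for 7 of 8. Precursor calls adjusted over the list alone numbered 7 (camera adjusted p = 0.00167, adjusted p = 0.319 with an estimated correlation). Microglial genes were lower for 15 of 18, including Aif1 (-4.29 ± 0.44). Microglial calls adjusted over the list alone numbered 16 (camera adjusted p = 1.24e-06, adjusted p = 0.279 with an estimated correlation). GABAergic neuron markers were lower for 12 of 13, with Slc32a1 (-3.03 ± 0.49), the gene of the vesicular GABA transporter. GABAergic marker calls adjusted over the list alone numbered 13 (camera adjusted p = 3.74e-04, adjusted p = 0.279 with an estimated correlation). Thalamic and hippocampal neuron markers were lower for 9 of 12 and higher for 1, with Ramp3 (-4.27 ± 0.27). Thalamic and hippocampal calls adjusted over the list alone numbered 10 (camera adjusted p = 0.00170, adjusted p = 0.279 with an estimated correlation). Choroid plexus and ependymal genes split 2 higher and 11 lower of 14. Choroid plexus and ependymal calls adjusted over the list alone numbered 13 (camera adjusted p = 0.0127, adjusted p = 0.279 with an estimated correlation). Transthyretin, Ttr (-6.74 ± 0.60), had the largest fall among genes at 10 CPM or more that shift by less than 1 between gene lists. Blood genes (0 of 3 higher and 2 lower, 3 adjusted over the list alone; camera adjusted p = 0.166), endothelial and mural genes (3 of 19 higher and 3 lower, 5 adjusted over the list alone; camera adjusted p = 0.946, adjusted p = 0.0424 in paired pools with a block), dopamine and serotonin neuron genes (3 of 7 higher and 3 lower, 6 adjusted over the list alone; camera adjusted p = 0.207; median -1.46, mean -0.37, test up) and sex-linked genes (0 of 5 higher and 3 lower, 3 adjusted over the list alone; camera adjusted p = 0.408; 2 inputs were of males only) did not pass the main test. Sst, the somatostatin gene, stood at 3.85 ± 3.11 CPM against 22.6 ± 5.93 CPM (-2.56 ± 0.48), with 10.5 CPM in 1 IP, saline-injected saccharin replicate 2. In the 4 libraries of paired pools Sst was not called, with a block (adjusted p = 0.311) or without.

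Pan-neuronal genes divided evenly in this comparison (6 of 24 higher and 7 lower, 13 adjusted over the list alone; camera adjusted p = 0.877), with Rbfox3 (1.38 ± 0.16) higher and Elavl2 (-2.31 ± 0.19) lower. Genes of nuclear-encoded oxidative phosphorylation leaned higher (22 of 81 higher and 6 lower, 27 adjusted over the list alone; camera adjusted p = 0.0273, adjusted p = 0.677 with an estimated correlation), as did histone genes (28 of 51 higher and 2 lower, 32 adjusted over the list alone; camera adjusted p = 0.00170, adjusted p = 0.521 with an estimated correlation), while proteasome genes (6 of 38 higher and 2 lower, 8 adjusted over the list alone; camera adjusted p = 0.207, adjusted p = 0.00668 in paired pools with a block), cytosolic ribosomal protein genes (5 of 80 higher and 14 lower, 12 adjusted over the list alone; camera adjusted p = 0.497) and unfolded protein response genes (3 of 22 higher and 1 lower, 3 adjusted over the list alone; camera adjusted p = 0.487) did not differ by the main test. Immediate early genes split 4 higher and 13 lower of 24, with Nptx2 (2.33 ± 0.20) higher and Dusp6 (-2.45 ± 0.21) lower. Immediate early calls adjusted over the list alone numbered 19 (camera adjusted p = 0.131, adjusted p = 0.00668 in paired pools with a block). IPs of the ChAT line were counted on all 3 gene lists, and 342 of the called genes also differed between lists within the ChAT IPs, among them the natriuretic peptide gene Nppa (shift of 3.46; adjusted p = 0.121 in paired pools with a block). Nos1 was not called (1.03 ± 0.49, adjusted p = 0.0901), but it was with DESeq2, with a term for the gene list and in baseline libraries alone. It stood at 85.1 to 94 CPM in IPs on list 1 and 80.9 to 85.7 CPM on list 3. The inputs, on list 1, held 31.3 to 41.9 CPM. Only the IPs on list 2 were lower, at 12.6 and 14.5 CPM without nicotine. The missing call may therefore rest on the list.

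**Figure D1:**
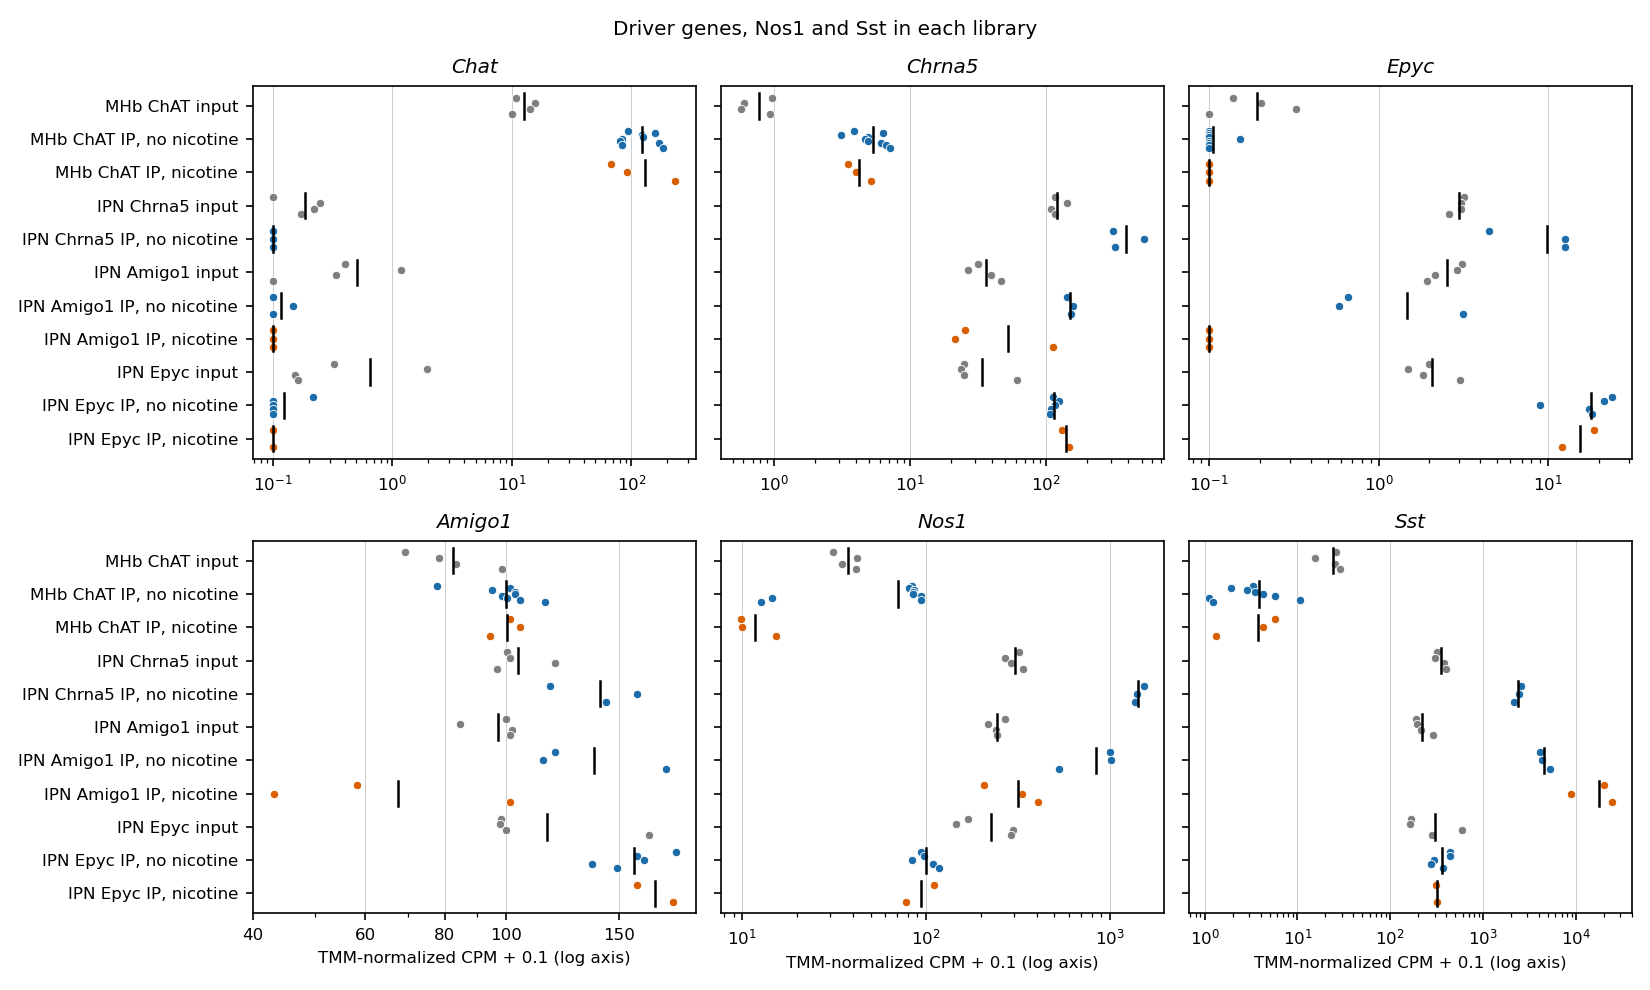
Level of Chat, Chrna5, Epyc, Amigo1, Nos1 and Sst in each library (CPM without TMM scaling, though the axis label names it, on a log axis). Each point is 1 library, with input in grey, IP without nicotine in blue and IP with nicotine in orange. Black lines are group means. Chat stood at 125 CPM on average over all 12 ChAT IPs against 12.6 CPM in habenula inputs. Sst stood at 4560 CPM in Amigo1 IPs without nicotine against 365 CPM in Epyc ones.

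In the IPN, neurons of the Chrna5 line were rich in transcripts for somatostatin and for neuronal nitric oxide synthase. Sst (chr16:23889573-23890958) stood at 2519.5 ± 188 CPM in 3 IPs against 339 ± 51.2 CPM in 4 inputs (2.89 ± 0.14, adjusted p = 8.46e-09), and Nos1 (chr5:117781032-117958840) at 1511 ± 87.8 against 294 ± 34.3 CPM (2.36 ± 0.13, adjusted p = 2.19e-08). The driver gene Chrna5 (chr9:54980880-55007779) was higher by 1.80 ± 0.17 and Epyc, a small proteoglycan gene, by 1.91 ± 0.40. Amigo1 was higher by 0.56 ± 0.15. Of 14385 genes, 2037 were higher in the IP and 2703 lower, and 2551 of these had an estimated absolute log2 difference of at least 1.

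Nitric oxide and cGMP genes were higher for 7 of 17 members and lower for 0. cGMP pathway calls adjusted over the list alone numbered 7 (camera adjusted p = 9.75e-05, adjusted p = 0.0547 with an estimated correlation). Beside Nos1 these included the phosphodiesterases Pde1c (1.16 ± 0.15) and Pde1b (1.05 ± 0.13) and a soluble guanylate cyclase subunit, Gucy1a3 (1.10 ± 0.15). Pan-neuronal genes were higher for 17 of 24 and lower for 1, with Syt1 (0.87 ± 0.13) and Vamp2 (0.76 ± 0.11), which act in vesicle release. Pan-neuronal calls adjusted over the list alone numbered 19 (camera adjusted p = 3.01e-05). GABAergic markers split 5 higher and 4 lower of 11 (9 adjusted over the list alone; camera adjusted p = 0.110, adjusted p = 0.00491 in paired pools with a block; median 0.25, mean -0.95, test up): Pax7 (2.29 ± 0.13), Otp (2.03 ± 0.14) and Slc32a1 (1.63 ± 0.13) were higher and the midbrain factor Tal1 (-3.81 ± 0.33) lower. Glutamatergic markers split 1 higher and 3 lower of 7, led by the vesicular glutamate transporter Slc17a6 (-3.77 ± 0.22). Glutamatergic marker calls adjusted over the list alone numbered 4 (camera adjusted p = 0.0253, adjusted p = 0.136 with an estimated correlation). Nicotinic subunits split 4 higher and 4 lower of 9, with Chrna2 (1.77 ± 0.17) and Chrna3 (1.52 ± 0.14) higher and Chrnb3 (-2.88 ± 0.22) lower. Nicotinic subunit calls adjusted over the list alone numbered 9 (camera adjusted p = 0.284). Dopamine and serotonin neuron genes were lower for 11 of 12 and higher for 1, with the dopamine transporter Slc6a3 (-4.20 ± 0.18) and Aldh1a1 (-4.60 ± 0.20). Dopamine and serotonin marker calls adjusted over the list alone numbered 12 (camera adjusted p = 2.25e-22).

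Every tested astrocyte (16), oligodendrocyte (18) and oligodendrocyte precursor (8) marker was lower in the Chrna5 IP, with the same 16, 18 and 8 genes adjusted over the list alone (camera adjusted p = 1.74e-36, 1.41e-44 and 1.84e-18; adjusted p = 0.00101, 0.0211 and 0.00730 with an estimated correlation). Microglial genes (0 of 18 higher and 17 lower, 18 adjusted over the list alone; camera adjusted p = 2.03e-10) and endothelial and mural genes (1 of 19 higher and 14 lower, 15 adjusted over the list alone; camera adjusted p = 2.67e-06, adjusted p = 0.0557 with an estimated correlation) were lower as well, the latter led by the pericyte gene Rgs5 (-4.40 ± 0.27). Genes of oxidative phosphorylation were higher for 53 of 78 and lower for 0, with Ndufa4 (1.18 ± 0.16) and Atp5g3 (1.07 ± 0.17). Oxidative phosphorylation calls adjusted over the list alone numbered 60 (camera adjusted p = 9.18e-12, adjusted p = 0.221 with an estimated correlation). Proteasome genes leaned the same way (16 of 37 higher and 1 lower, 19 adjusted over the list alone; camera adjusted p = 7.63e-04). Among the largest rises, Pou2af1 (chr9:51213708-51240080), a B cell coactivator, stood at 67.9 ± 40.2 CPM against 0.0752 ± 0.0738 CPM (9.58 ± 0.53), ahead of Fam46c (4.50 ± 0.59), the transcription factor Irf4 (4.36 ± 0.31) and the cyclin Ccnd2 (3.99 ± 0.30). Immunoglobulin Ighg1 had 1670 counts in the 3 IPs against 4 in the 4 inputs of the line, while the more abundant Ighm was lower in the IP (-0.83 ± 0.28) and Igkc was not called. Lmx1a, a transcription factor of midbrain dopamine neurons, was among the largest falls (-7.49 ± 0.69).

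Inputs of the Chrna5 line differed from the other 8 IPN inputs in 4 of 15017 genes, in a comparison chosen after the levels of the driver gene were seen. Chrna3 (2.68 ± 0.17, adjusted p = 2.50e-08), Chrnb4 (2.60 ± 0.20, adjusted p = 3.27e-07) and Chrna5 (1.77 ± 0.21, adjusted p = 4.17e-04), adjacent nicotinic genes between positions 54980880 and 55048779 of chr9, were higher, and Rpgrip1l (chr8:91217030-91313262), a ciliary gene, was lower (-1.03 ± 0.17, adjusted p = 0.0304). The call of Rpgrip1l was lost on leaving out any 1 of 8 libraries. Chrna5 stood at 119 ± 11.5 CPM in the 4 inputs of its line against 34.9 ± 14.3 CPM. None of 17 tested neighbours within 1 Mb was called. The enrichment of Chrna5 in the IP of its own line was measured against this raised input. DESeq2 called 11 genes.

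**Figure D2:**
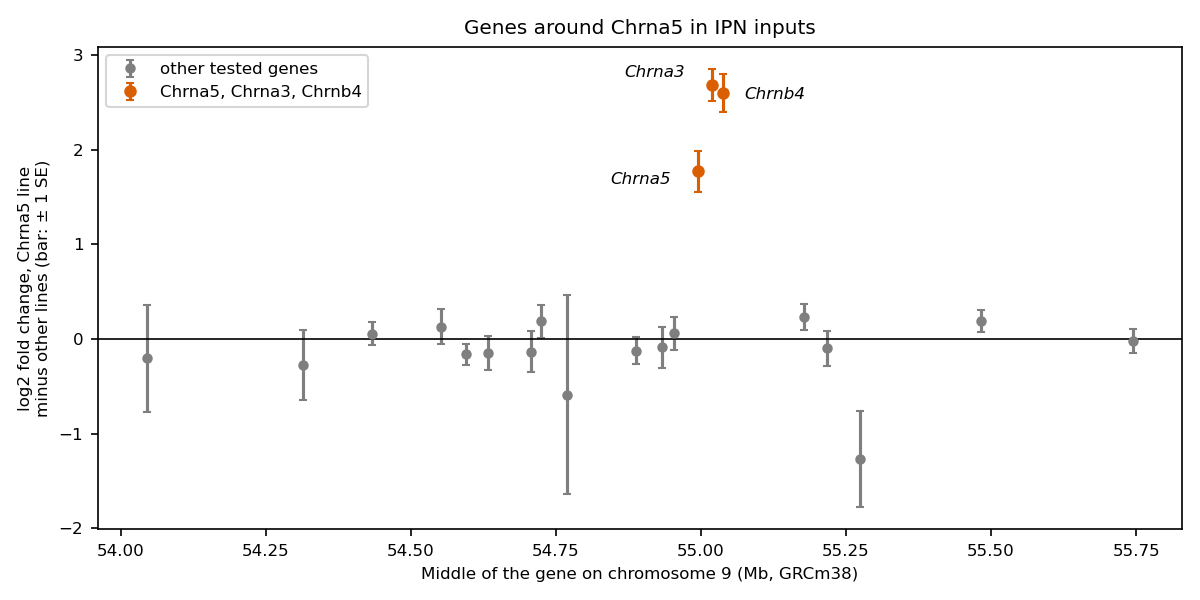
Log2 fold change ± SE of tested genes around Chrna5 on chromosome 9 (GRCm38 position on the horizontal axis), Chrna5-line inputs (4) against the other IPN inputs (8). Chrna5, Chrna3 and Chrnb4 stand at 1.77, 2.68 and 2.60, while the 17 neighbours have a median of -0.0981.

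Amigo1-line neurons of the IPN were also rich in transcripts of Sst and Nos1. Sst stood at 4775 ± 786 CPM in 3 IPs against 214 ± 38.4 CPM in 4 inputs (4.48 ± 0.17, adjusted p = 9.09e-07) and Nos1 at 880.4 ± 269 against 236 ± 19.8 CPM (1.90 ± 0.20, adjusted p = 1.26e-04). IPs and inputs were counted on different gene lists, between which Sst and Nos1 shifted by -2.70 and -2.78 in ChAT IPs (list 2, of the IPs here, minus list 1). Chrna5 was higher by 2.18 ± 0.19, and the driver gene Amigo1 (chr3:108186335-108192286), an adhesion molecule and potassium channel partner, by 0.62 ± 0.18 (adjusted p = 0.0303; 0.115 in paired pools with a block). The call of Amigo1 was also lost on leaving out any 1 of the 4 inputs. Amigo1 stood at 84.3 CPM in 1 input of the line, baseline replicate 2, apart from the rest of its group. Of 14506 genes, 2011 were higher and 2431 lower. 2537 were called in paired pools with a block (3094 in the same libraries without it) and 2774 when genes that shift between gene lists were left out.

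Nitric oxide and cGMP genes were higher for 12 of 17 members and lower for 0: besides Nos1, the cGMP-dependent kinase Prkg1 (3.29 ± 0.18), with a shift of 1.24 between gene lists, and the phosphodiesterases Pde5a (3.09 ± 0.32) and Pde1c (1.88 ± 0.15) were higher. cGMP pathway calls adjusted over the list alone numbered 14 (camera adjusted p = 1.16e-08, adjusted p = 0.191 with an estimated correlation). Among nicotinic subunits 4 of 9 were higher and 3 lower, with Chrna2 (2.58 ± 0.16), Chrna3 (2.22 ± 0.21) and Chrnb4 (1.92 ± 0.29). Nicotinic subunit calls adjusted over the list alone numbered 7 (camera adjusted p = 0.00933, adjusted p = 0.293 with an estimated correlation). GABAergic markers split 4 higher and 6 lower of 11, with Slc32a1 (1.36 ± 0.15) higher. GABAergic marker calls adjusted over the list alone numbered 10 (camera adjusted p = 0.853). Neuropeptide genes split 6 higher and 11 lower of 28. Neuropeptide calls adjusted over the list alone numbered 21 (camera adjusted p = 0.815; median -0.55, mean -0.67, test up). The enkephalin precursor Penk (2.51 ± 0.18) was higher, and Adcyap1 (-4.07 ± 0.28) and Cbln4 (-3.44 ± 0.23) were lower. Lower genes included 15 of 16 astrocyte (camera adjusted p = 2.09e-15, adjusted p = 0.191 with an estimated correlation), 17 of 18 oligodendrocyte (camera adjusted p = 2.51e-17, adjusted p = 0.191 with an estimated correlation), 7 of 8 oligodendrocyte precursor (camera adjusted p = 4.86e-05, adjusted p = 0.191 with an estimated correlation) and 10 of 18 microglial markers (camera adjusted p = 1.10e-05, adjusted p = 0.191 with an estimated correlation), with 15, 17, 8 and 13 adjusted over the list alone. Dopamine and serotonin neuron genes were lower for 11 of 12, with the serotonin transporter Slc6a4 (-3.86 ± 0.23). Dopamine and serotonin marker calls adjusted over the list alone numbered 12 (camera adjusted p = 8.11e-11, adjusted p = 0.191 with an estimated correlation). Endothelial and mural genes split 1 higher and 5 lower of 19. Endothelial and mural calls adjusted over the list alone numbered 6 (camera adjusted p = 0.103, adjusted p = 0.0407 in paired pools with a block). Histone genes (21 of 42 higher and 3 lower, 28 adjusted over the list alone; camera adjusted p = 4.59e-04, adjusted p = 0.293 with an estimated correlation) and genes of oxidative phosphorylation (10 of 80 higher and 2 lower, 8 adjusted over the list alone; camera adjusted p = 0.0104, adjusted p = 0.821 with an estimated correlation) leaned higher.

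All Amigo1 and Epyc IPs were counted on another gene list than their inputs, and the genes with the largest differences, such as Zbed6, Ilk and Raver1, had counts on 1 of the lists only. Among genes that differed by less than 1 on the log2 scale between lists, the largest rises in the Amigo1 IP were of Cytip (9.39 ± 1.10), expressed in lymphocytes, Bhlha15 (6.09 ± 1.14), a secretory cell factor, Dbf4 (5.40 ± 0.68), a replication kinase subunit, and Fam46c (4.97 ± 0.57). The neural patterning factor Nkx2-2 (-5.27 ± 0.60) and Apln (-4.22 ± 0.56), which encodes a peptide hormone, had the largest falls along with Phkg1 (-4.78 ± 0.60). Of the 4442 calls, 552 were genes with such a shift.

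Neurons of the Epyc line were rich in Epyc itself, while Sst was not called. Epyc (chr10:97644068-97682454) stood at 18.3 ± 5.54 CPM in 5 IPs against 1.94 ± 0.716 CPM in 4 inputs (3.22 ± 0.37, adjusted p = 4.31e-06). Chrna5 was higher by 1.82 ± 0.27 and Amigo1 by 0.52 ± 0.18, a call lost on leaving out any 1 of 6 libraries. The saline pump input of the line stood apart from its other inputs with 60.4 CPM of Chrna5 and 167 CPM of Amigo1. Sst stood at 372 ± 71.4 against 294 ± 196 CPM and was not called (0.34 ± 0.30, adjusted p = 0.409) unless baseline input 4 was left out, and Nos1 was lower by 1.10 ± 0.20. Sst and Nos1 had shifts of -2.70 and -2.78 between gene lists (list 2, of the IPs, minus list 1, of the inputs). These are larger than both differences. The direction of Nos1 and the missing call of Sst may therefore rest on the list. Of 14064 genes, 2236 were higher in the IP and 2836 lower. 2880 of these had an estimated absolute log2 difference of at least 1, and 589 calls were of genes with a shift between lists.

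Oxidative phosphorylation genes were higher for 62 of 80 and lower for 2, with Atp5g3 (1.13 ± 0.12) and Ndufb8 (1.87 ± 0.23), the latter with a shift of 1.53. Oxidative phosphorylation calls adjusted over the list alone numbered 69 (camera adjusted p = 9.51e-12, adjusted p = 0.195 with an estimated correlation). Proteasome genes leaned higher too (15 of 37 higher and 1 lower, 21 adjusted over the list alone; camera adjusted p = 0.00869, adjusted p = 0.195 with an estimated correlation). Pan-neuronal genes split 12 higher and 4 lower of 24, with the vesicle gene Syp (1.08 ± 0.12) higher. Pan-neuronal calls adjusted over the list alone numbered 18 (camera adjusted p = 0.0524, adjusted p = 0.0305 in paired pools with a block). In the nitric oxide and cGMP list 7 of 17 were higher and 3 lower, with Nos1ap (1.77 ± 0.17) and Pde1c (1.34 ± 0.17). cGMP pathway calls adjusted over the list alone numbered 11 (camera adjusted p = 0.106, adjusted p = 0.0305 in paired pools with a block). GABA receptor subunits were lower for 8 of 16 and higher for 0, with Gabrg3 (-2.57 ± 0.25) and Gabrq (-1.42 ± 0.23). GABA receptor calls adjusted over the list alone numbered 8 (camera adjusted p = 0.00642, adjusted p = 0.456 with an estimated correlation, adjusted p = 0.0762 in paired pools with a block). Nicotinic subunits split 5 higher and 4 lower of 9: Chrnb4 (2.34 ± 0.24) was higher and Chrnb3 (-3.25 ± 0.28) and Chrna6 (-2.39 ± 0.22) lower. Nicotinic subunit calls adjusted over the list alone numbered 9 (camera adjusted p = 0.984; median 0.69, mean -0.089, test up). GABAergic markers split 4 higher and 5 lower of 10, with Pax7 (2.03 ± 0.20) and Gad1 (1.25 ± 0.14) higher. GABAergic marker calls adjusted over the list alone numbered 9 (camera adjusted p = 0.643; median -0.77, mean -0.39, test up). Among genes without a list shift, the largest rise was of Dbf4 (4.43 ± 0.71), a replication kinase subunit. Grhl3 (3.50 ± 0.69) and Arhgap19 (3.29 ± 0.48) followed, and the proliferation marker Mki67 (3.20 ± 0.60) came after them. Mn1 (3.17 ± 0.20), Bahcc1 (2.91 ± 0.31) and the transcription factor Tcf7l2 (2.83 ± 0.21) were also among the largest rises. Bahcc1 belongs to the set of 7 genes flagged below. Heyl (-5.40 ± 0.54), a Notch target, and Fabp7 (-4.39 ± 0.33), a radial glia and astrocyte gene, were among the largest falls.

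Lower in the Epyc IP were 16 of 16 astrocyte (camera adjusted p = 2.04e-17), 17 of 18 oligodendrocyte (camera adjusted p = 4.87e-28), 7 of 8 oligodendrocyte precursor (camera adjusted p = 1.22e-06, adjusted p = 0.103 with an estimated correlation) and 17 of 18 microglial markers (camera adjusted p = 4.17e-07), with 16, 17, 7 and 18 adjusted over the list alone. Dopamine and serotonin neuron genes were lower for 11 of 12 and higher for 1, with Ddc (-4.10 ± 0.21). Dopamine and serotonin marker calls adjusted over the list alone numbered 12 (camera adjusted p = 1.44e-14). Endothelial and mural (1 of 17 higher and 7 lower, 8 adjusted over the list alone; camera adjusted p = 0.00642, adjusted p = 0.195 with an estimated correlation) and choroid plexus genes (0 of 8 higher and 3 lower, 3 adjusted over the list alone; camera adjusted p = 0.0281, adjusted p = 0.195 with an estimated correlation) were lower too, and thalamic and hippocampal markers (0 of 10 higher and 5 lower, 5 adjusted over the list alone; camera adjusted p = 0.101, adjusted p = 0.0298 in paired pools with a block) had lower members too, and this list passed camera only in the paired pools.

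**Figure D3:**
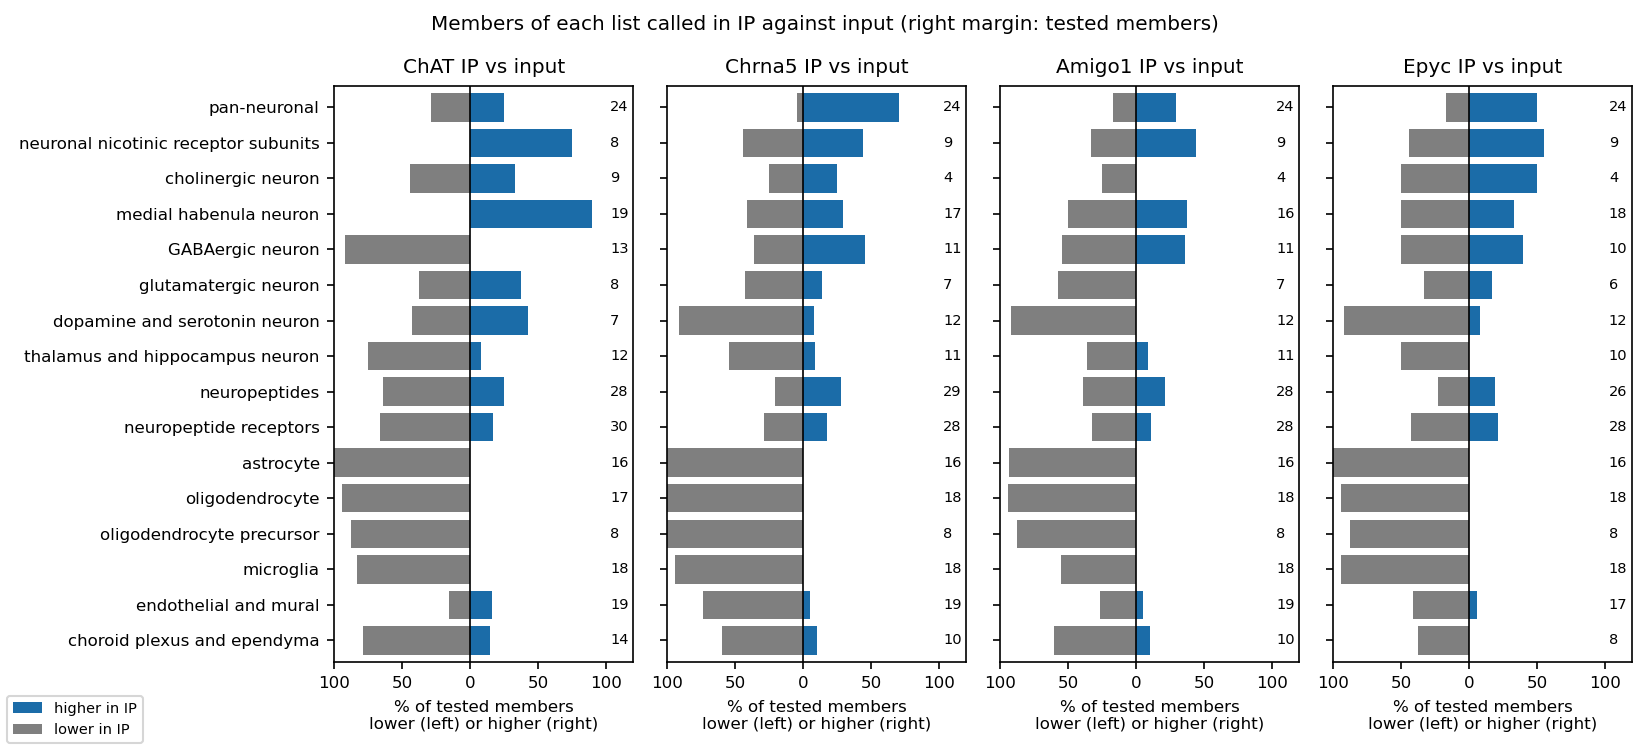
Share of tested list members that were higher (to the right) or lower (to the left) in the IP than in the input, in percent, for 16 gene lists and the ChAT, Chrna5, Amigo1 and Epyc lines; the number of tested members is at the right of each bar. Astrocyte members were lower for 16 of 16, 16 of 16, 15 of 16 and 16 of 16 in these lines, and MHb markers were higher for 17 of 19 in the ChAT line.

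The 3 IPN lines shared many enriched genes. Among 13743 genes tested in all 3, 630 were higher in every IP, against 43.97 for independent lists, and 1151 were lower in every IP, against 82.63. Amigo1 and Epyc share the difference in gene list between IP and input, which can add shared calls. RNA that enters every IP would be shared too, as would any difference between neurons and glia. Pou2af1, of the set flagged below, stood at 39.8 to 409 CPM in the 11 IPs without nicotine. It reached at most 0.551 CPM in the 12 inputs. The numbers for independent lists are therefore no baseline for a shared neuronal identity. Among 11490 genes with a list shift under 1, 554 were higher in every IP (38.49 for independent lists) and 782 lower (36.03). Pairwise, 932 genes were higher in both the Chrna5 and Amigo1 IPs (281.7 for independent lists), 1166 in the Chrna5 and Epyc IPs (315.7) and 1033 in the Amigo1 and Epyc IPs (298.7), with Fisher's exact test p at or below 1e-300, one-sided, for each pair, which treats genes as independent. Nicotinic and nitric oxide genes higher in all 3 included Chrna5 and the calcium-dependent phosphodiesterase Pde1c (1.16 ± 0.15, 1.88 ± 0.15 and 1.34 ± 0.17). With only calls of an estimated log2 difference above 1, 136 genes were higher in all 3.

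Set against each other, Amigo1 neurons held more Sst and Nos1, and Epyc neurons more Epyc (differences are Amigo1 minus Epyc). Sst stood at 4500.5 ± 732 CPM in 3 Amigo1 IPs against 363 ± 68.3 CPM in 5 Epyc IPs (3.63 ± 0.15, adjusted p = 2.12e-10), Nos1 at 830.1 ± 254 against 101 ± 12.8 CPM (3.05 ± 0.17, adjusted p = 3.54e-09), and Epyc at 1.36 ± 1.49 against 17.9 ± 5.36 CPM (-3.89 ± 0.64, adjusted p = 6.51e-04). Neither Chrna5 (0.37 ± 0.16, adjusted p = 0.153) nor the driver gene Amigo1 (-0.22 ± 0.18, adjusted p = 0.480) was called. Of 13834 genes, 700 were higher in Amigo1 and 692 in Epyc neurons. Tested as a difference of IP minus input between the lines, 618 genes were called, among them Sst (4.10 ± 0.43), Nos1 (2.97), Pde5a (5.46) and Epyc (-4.12). Of the calls between the IPs, 798 had an estimated absolute log2 difference of at least 1.

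Nitric oxide and cGMP genes were higher in Amigo1 neurons for 6 of 17 and lower for 1: Pde5a (5.92 ± 0.45), Prkg1 (2.76 ± 0.22) and Pde1a (2.01 ± 0.17) stood beside Nos1. cGMP pathway calls adjusted over the list alone numbered 11 (camera adjusted p = 8.55e-08, adjusted p = 0.191 with an estimated correlation). GABA receptor subunits were higher for 5 of 16 and lower for 1, with Gabrq (3.13 ± 0.20), Gabrg1 (2.86 ± 0.21) and Gabra2 (1.13 ± 0.21). GABA receptor calls adjusted over the list alone numbered 9 (camera adjusted p = 1.15e-04, adjusted p = 0.338 with an estimated correlation). Of 9 nicotinic subunits 4 were higher and 0 lower, with Chrna6 (2.15 ± 0.24), Chrnb3 (1.86 ± 0.38) and Chrna3 (1.21 ± 0.20). Nicotinic subunit calls adjusted over the list alone numbered 6 (camera adjusted p = 0.00371, adjusted p = 0.338 with an estimated correlation). Ionotropic glutamate receptor genes split 3 higher and 3 lower of 17, with Gria1 (1.87 ± 0.14) higher and Grik3 (-1.93 ± 0.29) lower. Glutamate receptor calls adjusted over the list alone numbered 8 (camera adjusted p = 0.583). Among neuropeptides, 5 of 26 were higher and 4 lower, including Vgf (2.22 ± 0.29) and Calca (2.53 ± 0.39). Neuropeptide calls adjusted over the list alone numbered 11 (camera adjusted p = 0.133). The receptor list gave 2 higher and 3 lower of 27, with the vasopressin receptor Avpr1a (4.27 ± 0.82) higher and the neurokinin receptor Tacr3 (-1.39 ± 0.25) lower. Peptide receptor calls adjusted over the list alone numbered 5 (camera adjusted p = 0.614). Voltage-gated channels divided 18 higher and 17 lower of 83. Ion channel calls adjusted over the list alone numbered 47 (camera adjusted p = 0.311).

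Epyc neurons were higher in 10 of 24 pan-neuronal genes and lower in 3, with the neurofilament Nefh (-1.63 ± 0.22) and Eno2 (-0.78 ± 0.13), and in 19 of 80 oxidative phosphorylation genes and lower for 0, with Atp5c1 (-0.87 ± 0.15) and Ndufb5 (-0.81 ± 0.13). Pan-neuronal calls adjusted over the list alone numbered 15 (camera adjusted p = 0.00296, adjusted p = 0.191 with an estimated correlation). Oxidative phosphorylation calls adjusted over the list alone numbered 24 (camera adjusted p = 8.55e-08, adjusted p = 0.536 with an estimated correlation). Nefh, Eno2 and Atp5c1 were not called as a difference of IP minus input. Cytosolic ribosomal protein genes were higher in Amigo1 neurons for 5 of 80. Ribosomal protein calls adjusted over the list alone numbered 0 (camera adjusted p = 5.31e-05, adjusted p = 0.767 with an estimated correlation). The proteasome (0 of 37 higher and 2 lower, 0 adjusted over the list alone; camera adjusted p = 0.0223, adjusted p = 0.345 with an estimated correlation) and histone lists (1 of 41 higher and 1 lower, 2 adjusted over the list alone; camera adjusted p = 0.0229, adjusted p = 0.665 with an estimated correlation) passed the camera test with few calls. Outside the lists Amigo1 neurons were higher in Slc44a3 (10.50 ± 0.77), a choline transporter-like gene, Mab21l2 (5.13 ± 0.37) and the ubiquitin ligase March1 (4.37 ± 0.22). Epyc neurons were higher in the phospholipase Pla2g2f (-6.76 ± 0.42), the CRH binding protein Crhbp (-4.01 ± 0.44), the serotonin receptor Htr1a (-3.12 ± 0.24) and the factors Nkx1-2 (-6.36 ± 0.55) and Lmo2 (-3.74 ± 0.51).

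**Figure D4:**
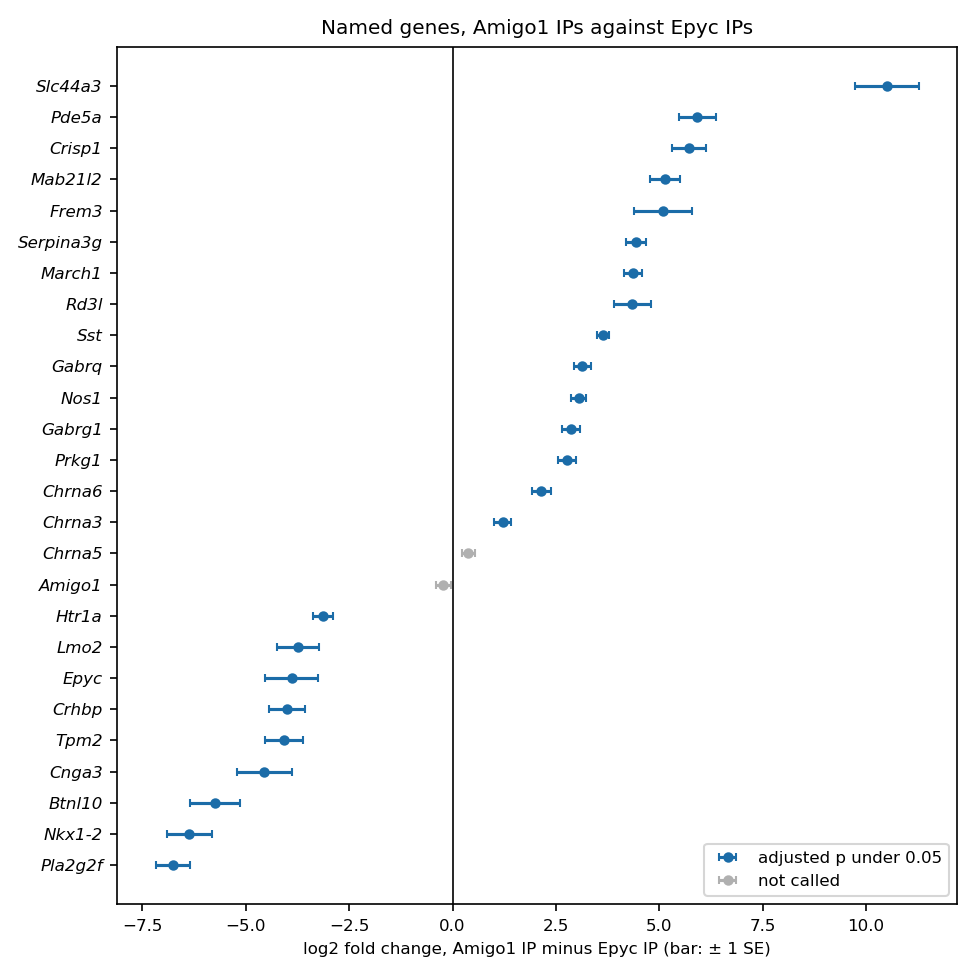
Log2 fold change ± SE (edgeR) of 26 named genes between Amigo1 IPs (3) and Epyc IPs (5); genes called at adjusted p < 0.05 are blue, others grey. Slc44a3 (10.50) and Pde5a (5.92) lie farthest to the Amigo1 side and Pla2g2f (-6.76) to the Epyc side.

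Nicotine in drinking water for 6 weeks gave no called gene in ChAT neurons in the main fit, though other settings called many. In the IPs of 2 nicotine pools against 2 saccharin pools, edgeR called 0 of 15547 genes, with 1095 at unadjusted p < 0.05, while DESeq2 called 504. Nicotinic receptor genes were not called (Chrna3 0.053 ± 0.20, Chrnb4 -0.061 ± 0.22, Chrna5 -0.37 ± 0.30; adjusted p = 1.00, 1.00 and 1.00), nor was Chat (-0.055 ± 0.32, adjusted p = 1.00). Astrocyte and oligodendrocyte markers leaned higher with nicotine and oxidative phosphorylation genes lower (camera adjusted p = 0.00132, 0.00132 and 0.00132; adjusted p = 0.939, 0.939 and 0.939 with an estimated correlation), with 0 members called over all genes and 0, 0 and 3 adjusted over the list alone. Nitric oxide and cGMP genes leaned higher and ribosomal protein genes (0 adjusted over the list alone; camera adjusted p = 0.0212, adjusted p = 0.939 with an estimated correlation) lower. cGMP pathway calls adjusted over the list alone numbered 1 (camera adjusted p = 0.0375, adjusted p = 0.939 with an estimated correlation). The 2 groups were counted on different gene lists, and Nos1 (-3.19 ± 0.92, adjusted p = 0.542) stood at 85.1 to 94 CPM in ChAT IPs on list 1, at 80.9 to 85.7 CPM on list 3 and at 9.78 to 15.2 CPM on list 2, the latter with and without nicotine. With a term for the gene list 55 genes were called and Sst turned from -0.022 ± 0.96 (adjusted p = 1.00) to 3.42 and was called. That term rests on the saline-injected saccharin pair alone, counted on lists 2 and 1, with Sst at 1.02 and 10.5 CPM. Without the term, the difference between these 2 lists entered the spread of the main fit. With the 4 uninjected libraries alone 971 were called (975 with a block for the replicate number, whose libraries share a sequencing lane in the labels), and without saline-injected saccharin replicate 1 or 2, 1024 or 1022.

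Amigo1 neurons of mice given nicotine and saccharin in water had IP libraries with fewer genes detected, and no gene was called. The 3 nicotine libraries had counts in 10515 to 10933 of the shared genes against 13367 to 15288 in 3 control libraries. The controls were of mice without saccharin water, so nicotine and saccharin cannot be separated. The labels also number the nicotine libraries 1916, 1918 and 1919, under another name, and the controls 762, 764 and 884. A difference between these sets of libraries cannot be separated either. The edgeR test called 0 of 12276 genes, with 1794 at unadjusted p < 0.05. DESeq2 called 967 (310 higher, 657 lower). Sst stood at 22377 ± 9222 CPM against 3567 ± 569 CPM (2.65 ± 0.34, adjusted p = 0.101). Chrna5 (-0.85 ± 0.73, adjusted p = 0.690) and Nos1 (-0.71 ± 0.40, adjusted p = 0.491) were not called. Pan-neuronal genes and oxidative phosphorylation genes (0 adjusted over the list alone; camera adjusted p = 0.00296, adjusted p = 0.843 with an estimated correlation) leaned higher, while histone (12 adjusted over the list alone; camera adjusted p = 1.38e-04, adjusted p = 0.485 with an estimated correlation), neuropeptide receptor (7 adjusted over the list alone; camera adjusted p = 0.00183, adjusted p = 0.485 with an estimated correlation) and endothelial and mural genes (4 adjusted over the list alone; camera adjusted p = 0.00317, adjusted p = 0.485 with an estimated correlation) leaned lower. Pan-neuronal calls adjusted over the list alone numbered 6 (camera adjusted p = 2.01e-05, adjusted p = 0.485 with an estimated correlation). Levels of the habenular genes were uneven over the nicotine libraries: Pou4f1 stood at 147 CPM in replicate 4 and at 0.137 CPM or less in the others, and Gng8 at 64 and 7.99 CPM in replicates 1 and 4 and 0 in replicate 3. Weighting the libraries by quality (limma voom) gave 85 calls (78 higher, 7 lower), and leaving out nicotine replicate 3 gave 22 (22 higher, 0 lower). Sst was called in both, and by DESeq2.

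In Epyc neurons, nicotine by pump gave 1 called gene. Cdr1 (chrX:61184005-61185558), whose locus also gives a circular antisense RNA that binds miR-7, was lower by 1.47 ± 0.21 on the log2 scale (533 ± 32.7 CPM in 2 nicotine IPs against 1478 ± 339 CPM in 5 controls; adjusted p = 0.0234). These libraries carry no strand information, so the gene and its antisense partner cannot be told apart. Of 13810 genes 1330 had unadjusted p < 0.05, and DESeq2 called 58. Among nicotinic subunits, Chrna5 (0.33 ± 0.16, adjusted p = 0.519) and Chrnb4 (-0.19 ± 0.24, adjusted p = 0.849) were not called, nor was Epyc (-0.19 ± 0.36, adjusted p = 0.907). Oxidative phosphorylation genes leaned higher and choroid plexus genes lower (0 adjusted over the list alone; camera adjusted p = 0.0470, adjusted p = 0.638 with an estimated correlation). Oxidative phosphorylation calls adjusted over the list alone numbered 0 (camera adjusted p = 2.19e-07, adjusted p = 0.818 with an estimated correlation). The call of Cdr1 was lost on leaving out any one of the 4 baseline controls or nicotine replicate 2, and 73 genes were called without nicotine replicate 1. With the saline pump library alone as control, the matched treatment, Cdr1 was not called and 1 other gene was. Cdr1 stood at 1000 CPM in that library.

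The test of the Amigo1 against the Epyc response to nicotine called 1034 of 14290 genes. Of these, 192 had a positive and 842 a negative difference (Amigo1 response minus Epyc response). The fit takes 1 spread per gene over all groups, though spreads were unlike. The common biological coefficient of variation was 1.08 in the Amigo1 nicotine fit, 0.395 in the Epyc one and 0.806 here. Amigo1 nicotine libraries were thus tested here with a lower spread than in their own fit, which called 0 genes. Route of nicotine also differed between the lines (water and pump), and only the Amigo1 nicotine mice had saccharin. The Amigo1 nicotine libraries also form a later-numbered set in the labels. Levels in this paragraph are CPM without TMM scaling, so they do not give the fitted differences, which used scaled counts. Cdr1 stood at 1690 and 16700 CPM in Amigo1 control and nicotine IPs and at 1490 and 523 CPM in Epyc ones (difference of differences 5.55 ± 0.80, adjusted p = 0.00409). Sst (2.84 ± 0.42, adjusted p = 0.00418) stood at 4560 and 17700 CPM in Amigo1 and at 365 and 315 CPM in Epyc. The demethylase Tet1 (3.83 ± 0.92, adjusted p = 0.0234) stood at 161 and 606 CPM in Amigo1 and 151 and 67.7 CPM in Epyc, and the morphogen Shh (3.69 ± 0.74, adjusted p = 0.0105) at 12.5 and 122 against 13.3 and 16.4 CPM. Many of the lower genes had 0 counts in all Amigo1 nicotine libraries: the actin regulator Coro1a stood at 30.7 CPM in Amigo1 controls and under 0.0442 CPM with nicotine (a floor of 3 counts over the 3 libraries together), a ratio of at least 694, and the NF-kB subunit Rel at 11.9 CPM in controls, a ratio of at least 269. As these libraries detected 10515 to 10933 genes against 13367 to 15288 in controls, such zeros may be lost molecules, which the floor does not cover. TMM factors of this fit were 0.6527 to 0.7186 in Amigo1 nicotine and 1.123 to 1.173 in Amigo1 control libraries. Scaled ratios would thus be lower than these. Pan-neuronal genes (6 of 24 higher and 0 lower, 7 adjusted over the list alone; camera adjusted p = 2.09e-06, adjusted p = 0.220 with an estimated correlation) were higher, with Nefm (3.38 ± 0.57) and Vamp2 (1.58 ± 0.28). Histone (1 of 43 higher and 10 lower, 18 adjusted over the list alone; camera adjusted p = 1.13e-04, adjusted p = 0.294 with an estimated correlation), neuropeptide receptor (0 of 27 higher and 5 lower, 6 adjusted over the list alone; camera adjusted p = 0.0212, adjusted p = 0.338 with an estimated correlation), microglial (0 of 17 higher and 4 lower, 5 adjusted over the list alone; camera adjusted p = 0.0413, adjusted p = 0.220 with an estimated correlation) and endothelial and mural genes (0 of 16 higher and 3 lower, 4 adjusted over the list alone; camera adjusted p = 0.0212, adjusted p = 0.220 with an estimated correlation) were lower. Chrna2, a subunit typical of the IPN, was higher by 1.51 ± 0.37 (adjusted p = 0.0257). Chrna2, Tet1 and Shh lost their calls when either Epyc nicotine library was left out. Saline pump libraries alone as control leave 1 control library per line, so the calls could not be checked against matched controls. DESeq2 called 2142 (591 positive, 1551 negative) and limma voom with quality weights 81, of which 81 were positive and 0 negative. With simulated changes of 2-fold and 4-fold, this test recovered none.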

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

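The tests of B cells, of expression in labelled neurons, of nicotine, of extra gene copies and of MHb tissue, the second test of labelled neurons in the inputs, and the added tests of background were chosen only after the result was seen; the others were fixed before. In the IPN IPs without nicotine a set of 7 genes, led by Pou2af1, Irf4 and Fam46c, was enriched (9.58 ± 0.53 for Pou2af1 in the Chrna5 IP). In Amigo1 nicotine IPs Pou2af1 stood at 0 to 36.5, Irf4 at 0.215 to 1230 and Fam46c at 0 to 3.99 CPM. ChAT IPs averaged above MHb inputs in Pou2af1 (4.09 against 0.0719 CPM) and Irf4 (11 against 0.367 CPM), but not in Fam46c (1.93 against 4.41 CPM). RNA carried in with the antibody from antibody-producing cells was left open: 17 of 25 plasma cell markers were tested, with a median of 0.735, 6 higher (Ighg1 9.60, Mzb1 4.87) and 4 lower (Cd38 -4.28). B cells in the tissue might give such genes, but the highest B cell marker, Cd74, reached 11.3% of Pou2af1, which met the condition first set for this cause. Since Cd74 also marks microglia and stood at 0.00 ± 0.31 between IP and input, a second test was added, in which tested B cell markers had a median of -2.79 and none was higher, against it. GC content or length is an unlikely source, as 267 genes nearest in both had a median of -0.078 against 3.67 for the pattern. Expression in the labelled neurons stays open: Pou2af1 exceeded Sst by 6.69 on the log2 scale, which met the condition first set against it, but Sst bounds it only if unlabelled IPN cells make no Sst, which was not measured.

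Sst stood at 2.65 ± 0.34 on the log2 scale in Amigo1 nicotine against control IPs without passing the adjusted test. Less background RNA in these IPs could raise it, and this stays open. The 50 genes most enriched in Amigo1 over Epyc IPs had a median of -0.79, and 99 such genes at 100 CPM or more a median of 0.438, but both sets were picked in the control IPs, which lowers their medians. Picked on both Amigo1 groups alike, 409 genes had a median of 1.5 (SD 1.03), against 0.763 for all 2520 at 100 CPM or more; the bound set for this test was too weak, since 183 of the 409 lay within 1 of Sst or above. Few molecules in the libraries could too: Sst lay at the 95.7 percentile of 46 genes at 1000 CPM or more, inside their central 95% by rank. Its value lay above the computed upper end of that range (-1.65 to 2.58), by less than its SE, so this stays open. Nicotine itself, given with saccharin, gave an exact permutation p of 0.1, two-sided, which is the smallest that 3 against 3 libraries allow.

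Chrna5, Chrna3 and Chrnb4 stood above the other IPN inputs in inputs of the Chrna5 line. Extra copies of the cluster carried with the driver transgene would raise these genes and not their neighbours, consistent with a median absolute log2 difference of 0.15 over 17 neighbours within 1 Mb, none called. MHb tissue in the dissection is unlikely: Tac2 stood at 0.492% of the excess of Chrna3. More of the labelled neurons is unlikely too, as the 50 genes most enriched in the Chrna5 IP over all 12 IPN inputs had a median of 0.284 (SD 0.74), with 1 of them at 1.77 or more. The first such set, with -0.0981, was picked against these same inputs, which lowers its median.

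Libraries were also regrouped within each comparison, the real grouping included. As many genes as in the real grouping were called in 1 of 100 splits for ChAT IP against input (8125 genes, highest other 147), 1 of 35 for Chrna5 (4740, 0), 1 of 35 for Amigo1 (4442, 0), 1 of 100 for Epyc (5072, 1785 with 1 IP exchanged), 1 of 56 for Amigo1 against Epyc (1392, 0) and 1 of 100 for IPN against MHb inputs (5085, 887), so a random grouping of these libraries can be excluded at this number of splits, if pools are ignored. Among drawn splits that part IP and input of each paired pool, as the real one does, it was 1 of 21 for Epyc, and 1 of 8 for Chrna5, 1 of 8 for Amigo1 and 1 of 16 for ChAT, too few for a share under 0.05; the highest other was 0 in each. For Chrna5 line inputs it was 3 of 100 (4, 40), which decides nothing, as this grouping was chosen from levels in the same libraries. Splits with many genes, such as the 1785 and 887, lie close to the real grouping, and the 40 genes joined Amigo1 input 4, Chrna5 inputs 3 and 4 and the Epyc saline pump input, which points to structure among these samples. For Amigo1 nicotine all 10 splits gave 0 genes, the real one and the highest other alike, too few splits to tell.

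Dixon's test set 6 of 40 groups and measures apart, where chance gives about 1 in 20. They were Sst at 10.5 CPM in the saline-injected saccharin ChAT IP 2, 16793 genes with counts in the saline-injected saccharin ChAT input 2, Amigo1 at 84.3 CPM in the Amigo1 baseline input 2, Chat at 1.86 CPM in the Epyc baseline input 2, and Chrna5 at 60.4 and Amigo1 at 167 CPM in the Epyc saline pump input 2. The test of the Amigo1 against the Epyc response to nicotine called 1034 genes, with 1 spread per gene over groups of unlike spread. Positive log2 differences of named genes included 6.53 for Sirt4, 5.55 for Cdr1, 4.3 for Fam122a, 3.83 for Tet1, 3.78 for Map7, 3.69 for Shh, 3.56 for Zfhx3, 3.47 for Ccdc25 and 2.84 for Sst. With 0 counts in all Amigo1 nicotine libraries, the ratio of Amigo1 controls to a floor of 3 counts over these 3 libraries together (0.0442 CPM; 0.0996 to 0.206 CPM for each alone) was at least 627 for Cyp2t4, 590 for Cdc42ep1, 826 for Slc35a1, 484 for Wdr25, 609 for Agbl4, 694 for Coro1a, 437 for Ptges2, 269 for Rel and 30.9 for Epyc, which stood at 3.05 CPM in the saline pump control and 0.521 CPM on average in the baseline controls. These ratios are without TMM scaling, which would lower them, and the floor does not cover molecules lost before sequencing. IP minus input differed between these lines in 618 genes. Outside the shared symbols, Chrna5 IPs held 25.1 CPM of Ighg1, 5.04 of Igkv6-32, 3.66 of Ighg2b and 2.96 of Ighg2c. Ighm stood highest at 40.8 CPM but was lower than in input (-0.83, adjusted p = 0.0323), and Igkc at 23 CPM was not called (adjusted p = 0.241).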

How the results depend on the processing

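Settings added only after results were seen were the fits without shifted genes, on 1 gene list and with voom weights. Where a count moved by over 1.5 times, the cause was not tested. Keeping only calls with an estimated log2 difference of at least 1 left 4688 genes (ChAT), 2551 (Chrna5), 2880 (Epyc) and 798 (Amigo1 against Epyc). It left 136 of the 630 genes higher in all 3 IPN lines. These falls follow from the added cut. Saline-injected saccharin libraries alone gave 3401 genes in ChAT, and genes without a list shift 2774 in Amigo1. DESeq2 called 504 (ChAT nicotine), 967 (Amigo1 nicotine), 58 (Epyc nicotine), 2142 (difference of responses) and 11 genes (Chrna5 line inputs); voom weights gave 85 for Amigo1 nicotine and 81 for the difference of responses. Without a count filter 1 gene was called for Amigo1 nicotine. In ChAT nicotine a term for the gene list gave 55 genes and reversed Sst to 3.42, and the 4 uninjected libraries alone gave 971. Saline pump libraries alone as controls left 1 control library per line, too few to judge the difference of responses. IP minus input between Amigo1 and Epyc gave 618. Of 71 list tests 13 kept their call with an estimated correlation; fry passed 97, 58 of them shared. A gene list term was not fitted for Amigo1 and Epyc IPs against inputs. Levels under the floors of 0.0495 to 0.436 CPM were not detectable, and among named genes only Sst in ChAT nicotine was reversed by a setting. Epyc was called lower in the Amigo1 IP without the saline pump IP, and Nos1 was called in ChAT nicotine with DESeq2 and in the 4 uninjected libraries.

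Fits with the pool as a replicate block kept only pools with both fractions, so block and libraries changed together. They called 2537 genes in Amigo1, 5810 in ChAT, 5585 in Chrna5 and 5185 in Epyc; the same libraries without the block gave 3094, 3401 and 3905 in Amigo1, ChAT and Chrna5. Apart from the lists given with the results no other call of a list changed. Sst and Nppa in ChAT and Amigo1 in the Amigo1 and ChAT IPs were not called in these fits, and of these only Nppa was called in the same libraries without the block. Across other groups replicate numbers name no shared mice, though some share a sequencing lane in the labels, as both numbers do in ChAT nicotine: deviations correlated at -0.021 (Amigo1 and Epyc IPs), -0.089 (ChAT nicotine), 0.0065 (Amigo1 nicotine) and 0.022 (Epyc nicotine), and the block gave 722, 975, 12 and 1 genes.

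Leaving out 1 library gave 7078 to 8680 genes in ChAT, 3834 to 4417 in Chrna5, 3091 to 6467 in Amigo1, 4195 to 5388 in Epyc, 1037 to 1715 for Amigo1 against Epyc, 4026 to 5824 for IPN against MHb inputs and 3 to 6 for Chrna5 line inputs. ChAT nicotine ranged from 0 to 1024 (1024 and 1022 without saline-injected saccharin 1 and 2), and Amigo1 nicotine from 0 to 22 (22 without nicotine 3). Epyc nicotine ranged from 0 to 73: 73 without nicotine 1, and 0 without nicotine 2 or any of baseline 1 to 4. The difference of responses ranged from 459 to 3015: 672 without Amigo1 baseline 1, 683, 677, 670 and 688 without Epyc baseline 1 to 4, 459 and 505 without Epyc nicotine 1 and 2, and 2253, 3015 and 2807 without Amigo1 nicotine 1, 3 and 4.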

Other observations

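Inputs of the IPN and the MHb were compared only after the data were seen. The IPN dissection held genes of midbrain monoamine and GABAergic neurons, and the MHb dissection genes of habenula and thalamus. The serotonin transporter Slc6a4 (11.91 ± 0.29), the serotonin enzyme Tph2 (11.48 ± 0.34) and the dopamine transporter Slc6a3 (10.84 ± 0.31) were higher in 12 IPN inputs than in 4 MHb inputs, and 11 of 12 dopamine and serotonin neuron markers were (camera adjusted p = 1.46e-95, 11 adjusted over the list alone). Nicotinic subunits were higher for 5 of 9 (camera adjusted p = 7.87e-09, 5 adjusted over the list alone), with Chrna2 (9.29 ± 0.54) and Chrna6 (6.98 ± 0.28), and Chrna5 stood 6.52 ± 0.80 higher in the IPN. The raised inputs of the Chrna5 line add to the last value. In the 8 inputs of the Amigo1 and Epyc lines Chrna5 stood at 34.5 CPM, against 0.677 CPM in MHb inputs. GABAergic markers split 10 higher and 4 lower of 14, 14 adjusted over the list alone (camera adjusted p = 4.12e-10), with Slc32a1 (3.47 ± 0.16) and Gata3 (3.83 ± 0.23). MHb markers were lower for 12 of 19 (camera adjusted p = 3.32e-14, 13 adjusted over the list alone), with Nwd2 (-2.92 ± 0.11) and Zic1 (-6.82 ± 0.22); the peptide gene Tac2 (-7.21 ± 0.41) and Gpr151 (-7.83 ± 0.58), a receptor of habenular neurons, were lower too. Thalamic and hippocampal markers were lower for 9 of 12 (camera adjusted p = 8.31e-23, 10 adjusted over the list alone), with Prkcd (-6.12 ± 0.23) and Rora (-3.13 ± 0.09).

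Glial genes were also higher in the IPN inputs: astrocyte markers for 13 of 16 (camera adjusted p = 1.08e-06, 13 adjusted over the list alone), oligodendrocyte markers for 16 of 18 (camera adjusted p = 1.19e-09, adjusted p = 0.0748 with an estimated correlation, 17 adjusted over the list alone) and oligodendrocyte precursor markers for 8 of 8 (camera adjusted p = 3.24e-05, 8 adjusted over the list alone). GABA receptor subunits were lower for 10 of 16 and higher for 3, 13 adjusted over the list alone (camera adjusted p = 3.24e-05, adjusted p = 0.0824 with an estimated correlation). Region, line and driver transgene cannot be separated in this comparison, which called 2553 genes higher and 2532 lower of 15490.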
